A study of Homo sapiens with 42 samples.

How the data were processed

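The arrays compared RNA from T98G cells, a human glioblastoma line, that had been kept without serum for 72 h. Cells were left untreated or given platelet-derived growth factor BB (PDGF-BB, a mitogen) at 50 ng/ml for 0.5, 2 or 4 h. Some cells received cycloheximide, a blocker of protein synthesis, at 10 µg/ml from 0.5 h before PDGF-BB. Per the labels, polyadenylated RNA was amplified in 1 round and a pair of RNA samples was hybridised to each spotted two-colour array. Every replicate was measured on 2 arrays with the dyes exchanged, and the series design states that replicates were grown and harvested independently.

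The deposited values are log2 ratios of the first-named to the second-named RNA, with 1 column per array. The labels name limma as the authors' software without a version, and neither the labels nor the files state the background correction, the normalization or the rule that left values empty. Base 2 follows limma's usual ratio and is not stated in the files. The direction of the ratios was read from the values: FOS lay between 1.54 and 3.08 and EGR1 between 0.80 and 3.02 on every 0.5 h array, in both dye orientations. Array medians lay between -0.020 and 0.018 in the larger table and between -0.027 and 0.029 in the smaller.

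A larger table held 26880 spots on 32 arrays (16 replicates), and a smaller one held 23232 spots on 10 arrays (5 replicates, each the replicate numbered 3 of its comparison). Of the larger table's spots, 5587 were never measured, 4710 probes were measured on all arrays, and an array had between 8911 and 19836 measured spots. Of the smaller table's spots, 2309 were never measured and an array had between 19957 and 20665 measured spots. Both tables were tested separately, since they were made on different array designs. The comparisons rest on the larger table, and the smaller served as a check and, joined by gene symbol, as an alternative. Accessions printed on more than 10 spots (11 accessions) were averaged to 1 probe each, which left 26176 probes. Of these, 16867 carried 1 gene symbol, 172 carried several and 9137 carried none. Gene IDs of 16776 probes (99.5%) matched the human RefSeq gene table of assembly GRCh38.p14, which was used for current symbols and for which genes neighbour each other, and the probes covered 14941 genes. No coordinates are given, since the files name no genome build.

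The pair of dye-exchanged arrays was averaged to 1 value per replicate, and both orientations were needed. All 7 comparisons were fitted in 1 linear model, 1 coefficient each, with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, data.table, version 1.17.8). Coefficients were least-squares estimates for each pattern of missing values, with limma's moderated statistics (3.03 prior degrees of freedom). A probe was tested where at least 2 replicates had a value. PDGF at 2 h and at 4 h had 3 replicates and every other comparison had 2. The number of arrays and replicates limits the precision. P-values were two-sided and adjusted by Benjamini and Hochberg over the probes of a comparison, and a probe was called at an adjusted p under 0.05. The 3 differences between comparisons (PDGF at 2 h against 0.5 h, PDGF at 4 h against 2 h, and the cycloheximide effect at 4 h against 2 h) were contrasts of the same fit. Standard deviations (SD) are between replicates. Differences carry standard errors (SE).

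Induced probes had an adjusted p under 0.05 and a ratio of at least 1.5 (0.58 on the log2 scale) with PDGF. Those that passed at 0.5 h were named early, and those that passed at 2 or 4 h and not at 0.5 h were named later. A comparison in which a probe was not tested counted as not passed, at 0.5 h and with cycloheximide alike. A later probe was named resistant if PDGF with cycloheximide against untreated cells passed the same limits at such a time. It was named sensitive if it passed at none and was lower with cycloheximide than with PDGF alone at such a time, and undecided otherwise.

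For 24 gene lists, cameraPR was run on z-scores of the moderated statistics with a preset correlation of 0.01, 1 probe per gene, two-sided, for lists of at least 5 tested members, adjusted over the lists of a comparison. The probe with the fewest missing values stood for its gene. Members called are also counted with p adjusted over the list alone. The lists were immediate-early transcription factors, signalling feedback inhibitors, cytokines and chemokines, growth factors and matricellular signals, matrix, protease and adhesion genes, actin cytoskeleton targets of SRF, G1 cyclins and regulators, S phase and mitosis genes, sterol and lipid synthesis genes, NF-kB targets, ribosome biogenesis and MYC targets, cytosolic ribosomal proteins, quiescence and FOXO targets, unfolded protein and amino acid response genes, heat shock genes, interferon response genes, hypoxia and glycolysis genes, TGF-beta and BMP targets, replication-dependent histones, reference genes, and markers of leukocytes, epithelium, neurons, and astrocytes and glia. No list was taken from this study, and lists share members (IL6 and CXCL8 stand among cytokines and NF-kB targets).

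Genes named in the text follow a rule. It takes up to 10 genes per direction with the largest change among called probes with 1 symbol and the same sign in every replicate, a fixed panel of 27 response genes of which 21 were on the array, and up to 4 members of each list. Members of the induced classes, and the neighbouring pairs, were named after their values were seen. The groups, tests, class limits, lists, naming rule and the alternative analyses listed next were set before the data were examined. A further 3 alternatives (either dye orientation, a crossed replicate block and 1 probe per gene) were added after the data were seen.

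The alternative analyses were arrays re-centred and scaled to a common spread, only probes measured on every array, replicate number as a block (replicate block), 1 model of the 6 RNA conditions, only a comparison's own replicates in the fit, single arrays with a dye term (duplicateCorrelation, 0.489), both tables joined, robust empirical Bayes, each replicate left out, a ratio of 2 or none for the classes, and for the lists an estimated correlation, fry, the mean over a gene's probes and the replicate block.

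The fit was tested on simulated data. Of probes changed 2-fold, it recovered 94.0% for PDGF at 0.5 h (11391 probes), 95.5% at 2 h (13983) and 94.0% at 4 h (12492). It recovered 91.0% and 88.1% for PDGF with cycloheximide against untreated cells at 2 h (12804) and 4 h (13151), and 97.0% and 89.6% against PDGF alone (8848 and 12490). For the 3 differences it recovered 89.6% (10357), 89.6% (11462) and 83.6% (8383), and 0 probes had the wrong sign in these limma fits of simulated data. At 1.5-fold, the limit of the classes, it recovered 62.7% for PDGF at 0.5 h, 88.1% at 2 h and 76.1% at 4 h. A response of that size at 0.5 h was thus missed more often and could be named later. The simulation gave every comparison the same spread for a probe.

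The planned comparison of gene architecture between classes was not run, since the reference held gives no exon structure and its assembly cannot be matched to the files. No sample received cycloheximide without PDGF-BB.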

Results

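RNA levels in serum-starved T98G glioblastoma cells were compared at 0.5, 2 and 4 h after PDGF-BB, and at 2 and 4 h after PDGF-BB in the presence of cycloheximide. Each array carried a pair of RNA samples, so every value is a log2 ratio between conditions. PDGF at 2 h and at 4 h was set against untreated cells in 3 replicates. PDGF at 0.5 h, PDGF with cycloheximide against untreated cells at 2 and 4 h, and PDGF with cycloheximide against PDGF alone at 2 and 4 h had 2 replicates each in the larger table. The question behind the design was which genes respond to the growth factor at once, which respond later, and which of the later ones need new protein synthesis.

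**Figure D1:**
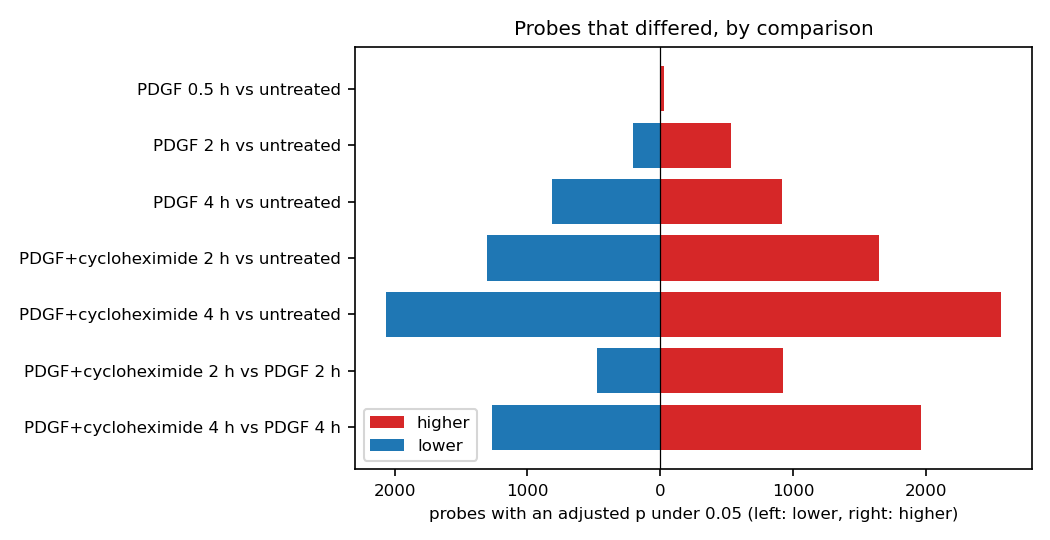
Number of probes with an adjusted p under 0.05 in each of the 7 comparisons, bars to the right for higher and to the left for lower in the first-named condition. Counts ran from 29 higher and 1 lower at 0.5 h of PDGF to 2569 higher and 2065 lower at 4 h of PDGF with cycloheximide.

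PDGF for 0.5 h raised the classic immediate-early genes of growth factor signalling. The orphan nuclear receptor NR4A2 rose most (3.36 ± 0.52, SD, n = 2, adjusted p = 0.0049, 10.3-fold), ahead of the secreted matricellular protein CCN1 (2.96 ± 0.48), the AP-1 subunit FOS (2.82 ± 0.20, adjusted p = 2.7e-05) and the MAP kinase phosphatase DUSP1 (2.55 ± 0.03, adjusted p = 6.9e-06). FOSB (2.47 ± 0.66), IL6 (2.44 ± 0.49), EGR1 (2.35 ± 0.68), NR4A1 (2.32 ± 0.55), ATF3 (2.19 ± 0.06) and BHLHE40 (2.07 ± 0.25) rose as well, each with n = 2. In all, limma called 29 probes higher and 1 lower of 11391 (365 at an unadjusted p under 0.05). With arrays re-centred and scaled it called 57 higher and 10 lower. The probe that was lower carried no gene symbol. MYC (0.78 ± 0.40), HBEGF (1.05 ± 0.19) and CXCL8 (1.02 ± 0.67) had positive values at n = 2 that did not pass. The call of NR4A2 ended when either replicate was left out, and the comparison then had 6 calls without replicate 1 and 11 without replicate 2.

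Immediate-early transcription factors were the list with the largest shift at 0.5 h among the lists tested. Of 26 tested, 13 rose, 0 fell and 13 were not called by limma, with 18 higher when adjusted over the list alone (median 1.06, list test adjusted p = 3.4e-53, and adjusted p = 1.2e-07 with an estimated correlation). Signalling feedback inhibitors had 5 of 25 higher (10 adjusted over the list alone, list test adjusted p = 1.6e-24, and adjusted p = 8.9e-06 with an estimated correlation), among them DUSP1, ZFP36 (1.93 ± 0.26), DUSP5 (1.59 ± 0.05) and GADD45B (1.58 ± 0.80). Of 12 cytokines and chemokines, IL6 alone was called (3 adjusted over the list alone, list test adjusted p = 1.2e-10, and adjusted p = 0.00012 with an estimated correlation). NF-kB targets had 1 of 22 higher, again IL6 (5 adjusted over the list alone, list test adjusted p = 9.1e-10), and adjusted p = 0.19 with an estimated correlation. Growth factors and matricellular signals had 1 of 14 higher, CCN1 (2 adjusted over the list alone, list test adjusted p = 0.00022). This list had adjusted p = 0.19 with an estimated correlation. Matrix, protease and adhesion genes had 1 of 26 higher, the urokinase gene PLAU (1.81 ± 0.15, 2 adjusted over the list alone, list test adjusted p = 0.0054), and adjusted p = 0.37 with an estimated correlation. Hypoxia and glycolysis genes (16 tested, 0 called, list test adjusted p = 0.011) and TGF-beta and BMP targets (9 tested, 0 called, list test adjusted p = 0.024) passed the list test without a called member. Hypoxia and glycolysis genes had adjusted p = 0.37 with an estimated correlation, and TGF-beta and BMP targets had adjusted p = 0.19 with an estimated correlation.

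At 2 h of PDGF, CCN2, a matricellular relative of CCN1, rose most (3.01 ± 0.14, n = 3, adjusted p = 0.00018, 8.08-fold). NR4A3 (2.98 ± 0.21), the WNT antagonist DKK1 (2.58 ± 0.38), the EGF receptor ligand HBEGF (2.44 ± 0.22, adjusted p = 8.2e-05), IL6 (2.38 ± 0.21) and CCN1 (2.28 ± 0.13) followed, each with n = 3. The cell cycle inhibitor CDKN1B fell most (-1.29 ± 0.53, n = 3, adjusted p = 0.016), ahead of the ephrin receptor EPHA4 (-1.15 ± 0.33) and MYLIP (-1.10 ± 0.35). CCND1, the G1 cyclin on which mitogens act, rose by 1.06 ± 0.28 (n = 3, adjusted p = 0.017), and MYC rose by 1.64 ± 0.45 (n = 3, adjusted p = 0.0047). FOS was at 0.03 ± 0.01 (n = 2), EGR1 at 0.13 ± 0.17 and JUN at 0.10 ± 0.12 (n = 3), none of them called. Over all 13983 probes, 533 were higher and 206 lower, of which 263 and 20 by at least 1.5-fold. The split depends on the scaling: with arrays re-centred and scaled, 1338 were higher and 1011 lower. The count rested most on replicate 2, without which there were 100 calls, against 315 without replicate 1 and 424 without replicate 3, and CXCL8 (1.82 ± 0.76) lost its call whichever replicate was left out.

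Among the lists at 2 h of PDGF, immediate-early transcription factors had 13 of 30 higher (14 adjusted over the list alone, list test adjusted p = 1.4e-10). The list had adjusted p = 0.069 with an estimated correlation. NF-kB targets had 9 of 23 higher, among them CCL2 (1.81 ± 0.48, n = 2) and TNFAIP2 (1.15 ± 0.06, n = 3), with 15 adjusted over the list alone (list test adjusted p = 2.1e-10), and adjusted p = 0.11 with an estimated correlation. Growth factors and matricellular signals had 8 of 19 higher, including TGFB2 (1.02 ± 0.32, n = 3), and 10 adjusted over the list alone (list test adjusted p = 1.2e-08). As a list they had adjusted p = 0.069 with an estimated correlation. Of 20 SRF targets of the actin cytoskeleton, 5 rose (9 adjusted over the list alone, list test adjusted p = 2.5e-07), with adjusted p = 0.069 with an estimated correlation. Vinculin (VCL, 1.81 ± 0.44, n = 3), which anchors actin at focal adhesions, led them, followed by CNN2 (0.84 ± 0.47), CALD1 (0.70 ± 0.23) and ZYX (0.63 ± 0.31). Matrix, protease and adhesion genes had 8 of 30 higher, such as PLAU (2.00 ± 0.47, n = 2) and THBS1 (1.20 ± 0.25, n = 3), and 13 adjusted over the list alone (list test adjusted p = 2.5e-07). That list had adjusted p = 0.071 with an estimated correlation. Feedback inhibitors had 5 of 30 higher (10 adjusted over the list alone, list test adjusted p = 6.2e-07), with adjusted p = 0.069 with an estimated correlation. Sterol and lipid synthesis genes, targets of SREBP, had 4 of 18 higher (7 adjusted over the list alone, list test adjusted p = 6.2e-06). Their test gave adjusted p = 0.069 with an estimated correlation. The 4 genes were INSIG1 (1.16 ± 0.24, n = 3), STARD4 (0.89), CYP51A1 (0.81) and IDI1 (0.73, adjusted p = 0.0019). Cytokines and chemokines had 4 of 13 higher (6 adjusted over the list alone, list test adjusted p = 0.00011), with adjusted p = 0.069 with an estimated correlation.

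At 2 h of PDGF, ribosome biogenesis and MYC targets had 2 of 26 higher, RRP12 (0.58 ± 0.11) and NOLC1 (0.51 ± 0.09), with 6 higher and 1 lower adjusted over the list alone (list test adjusted p = 0.0019). The list then gave adjusted p = 0.32 with an estimated correlation. S phase and mitosis genes had a median of -0.09 and 1 of 25 lower, CCNB1 (-0.49 ± 0.12, n = 3, 1 adjusted over the list alone, list test adjusted p = 0.021), with adjusted p = 0.57 with an estimated correlation. Cytosolic ribosomal proteins had 2 of 33 lower (2 adjusted over the list alone, list test adjusted p = 0.040). This became adjusted p = 0.48 with an estimated correlation. TGF-beta and BMP targets had 2 of 11 higher, CCN2 and PMEPA1 (0.39 ± 0.19), with 4 higher and 1 lower adjusted over the list alone (list test adjusted p = 0.040), and adjusted p = 0.18 with an estimated correlation. Interferon response genes had 2 of 22 higher, GBP1 (1.88 ± 0.40, n = 3) and GBP2 (0.75), with 2 adjusted over the list alone, and the list test did not pass (adjusted p = 0.073). G1 cyclins and regulators had 2 of 17 higher and 1 lower, with the same counts adjusted over the list alone (list test adjusted p = 0.083). Of 22 unfolded protein and amino acid response genes and 13 heat shock genes, limma called 0.

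At 4 h of PDGF, DKK1 was raised most (2.39 ± 0.64, n = 3, adjusted p = 0.0019, 5.24-fold), with the interleukin 7 receptor IL7R (2.07 ± 0.06, n = 2), the protease inhibitor TFPI2 (1.90 ± 0.47, n = 3, adjusted p = 0.0011) and TMEM158 (1.74 ± 0.24, n = 2) next. TXNIP, a brake on glucose uptake that is high in resting cells, fell most (-2.04 ± 0.95, n = 3, adjusted p = 0.028), and the BMP decoy receptor BAMBI (-1.24 ± 0.20, adjusted p = 0.014) and the histone gene H2AC6 (-1.14 ± 0.21, adjusted p = 0.0009) fell with n = 3. HBEGF (1.40 ± 0.33) and CCN1 (1.36 ± 0.51) were still raised, while CCN2 (0.75 ± 0.24, n = 3, adjusted p = 0.080) and CXCL8 (1.23 ± 1.26, n = 3) were not called. Of 12492 probes, 921 were higher and 817 lower, 247 and 120 of them by at least 1.5-fold. These calls borrow their spread from the other comparisons: with only its own 3 replicates in the fit, limma called 0 probes (2368 at an unadjusted p under 0.05), and replicates 1 and 3 correlated at 0.18 across genes, which are not independent replicates. Left out singly, replicates 1, 2 and 3 gave 920, 716 and 1606 calls, and TXNIP lost its call without replicate 1 or 2.

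Ribosome biogenesis and MYC targets formed the list with the smallest p at 4 h. Of 24 tested, 14 rose, 0 fell and 10 were not called by limma, with 16 higher adjusted over the list alone (median 0.46, list test adjusted p = 2.7e-09). The test became adjusted p = 0.21 with an estimated correlation. The box C/D snoRNP protein NOP56 (0.84 ± 0.45), NOLC1 (0.80 ± 0.21, adjusted p = 0.001) and the polyamine enzyme ODC1 (0.75 ± 0.34), each with n = 3, were among them. Growth factors and matricellular signals had 7 of 21 higher, including BDNF (0.94 ± 0.32, n = 3), and 8 adjusted over the list alone (list test adjusted p = 0.00011), with adjusted p = 0.50 with an estimated correlation. SRF targets had 5 of 20 higher (10 adjusted over the list alone, list test adjusted p = 0.00014), led by VCL (1.29 ± 0.41, n = 3). For this list, limma gave adjusted p = 0.48 with an estimated correlation. Quiescence and FOXO targets had 8 of 27 lower and 2 higher, with 12 lower and 3 higher adjusted over the list alone (median -0.29, list test adjusted p = 0.0042), and adjusted p = 0.71 with an estimated correlation. The receptor gene PDGFRB (-0.87 ± 0.14, n = 3, adjusted p = 0.0023) and BCL6 (-0.78 ± 0.40, n = 2) fell with TXNIP, and ARRDC3 rose (0.89 ± 0.27, n = 3). Matrix, protease and adhesion genes had 9 of 31 higher and 1 lower, with 14 higher and 2 lower adjusted over the list alone (list test adjusted p = 0.0042). The list test had adjusted p = 0.71 with an estimated correlation. Their examples were TFPI2 and tissue factor (F3, 1.26 ± 0.20, n = 3). Of 21 hypoxia and glycolysis genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone, list test adjusted p = 0.044), with adjusted p = 0.71 with an estimated correlation. They included ADM (1.61 ± 0.71, n = 2), PFKP (0.75 ± 0.22, n = 3) and SLC2A1 (0.60 ± 0.18, n = 3).

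Other lists at 4 h held fewer calls. NF-kB targets had 3 of 18 higher (3 adjusted over the list alone, list test adjusted p = 0.040), among them SOD2 (1.51 ± 0.63, n = 2). This list had adjusted p = 0.75 with an estimated correlation. Cytosolic ribosomal proteins had 2 of 31 lower (0 of them adjusted over the list alone in limma, list test adjusted p = 0.044), with adjusted p = 0.71 with an estimated correlation. Replication-dependent histones had 1 of 6 lower, H2AC6 (1 adjusted over the list alone, list test adjusted p = 0.034), and too few complete members for an estimated correlation. Immediate-early transcription factors had 3 of 24 higher, MYC (0.91 ± 0.47), BHLHE40 (0.71 ± 0.26) and CSRNP1 (0.39 ± 0.06), each with n = 3 and 3 adjusted over the list alone. Their median (-0.04) and mean (-0.09) were negative while the list test pointed upward (adjusted p = 0.96), so no direction is given for them. Reference genes had 3 of 11 higher and 1 lower, from HPRT1 (0.47 ± 0.07, n = 3) to SDHA (-0.40 ± 0.31, n = 3), and the list test did not pass (adjusted p = 0.12). Of 25 S phase and mitosis genes and 14 G1 cyclins and regulators, limma called 0 at 4 h.

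Between 0.5 and 2 h, the 3 named genes that fell were immediate-early ones. FOS fell by 2.79 on the log2 scale (SE 0.19, adjusted p = 0.0011), DUSP1 fell by 1.93 (SE 0.16, adjusted p = 0.0013) and KLF6 fell by 1.56 (SE 0.13, adjusted p = 0.0064). SPATA13 (1.63, SE 0.12, adjusted p = 0.021), the kinase MAP2K3 (1.10, SE 0.15) and SERTAD1 (0.82, SE 0.10) were higher at 2 h. Of 10357 probes, 4 were higher and 3 lower (675 at an unadjusted p under 0.05). Other fits called more: 163 higher and 44 lower with arrays re-centred and scaled, 82 and 22 with a dye term, and 77 and 26 with only the comparison's own replicates. Without replicate 1 at 0.5 h limma called 0 higher and 3 lower, and without replicate 2 at 0.5 h it called 0 higher and 4 lower. The calls of SPATA13, MAP2K3 and SERTAD1 thus ended without either 0.5 h replicate, while those of FOS, DUSP1 and KLF6 held. Without replicate 2 at 2 h, 1 was higher and 2 lower. Without replicate 1 at 2 h, 4 were higher and 2 lower, and without replicate 3 at 2 h, 4 were higher and 1 lower. Not every fall thus kept its call when a 2 h replicate was left out. As lists, immediate-early transcription factors were lower at 2 h than at 0.5 h (median -0.58, list test adjusted p = 1.5e-05). The list had adjusted p = 0.29 with an estimated correlation. SRF targets (median 0.24) and ribosome biogenesis genes (median 0.28) were higher, each with list test adjusted p = 8.7e-06, and adjusted p = 0.22 with an estimated correlation.

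Between 2 and 4 h, CCN2 fell by 2.26 on the log2 scale (SE 0.37, adjusted p = 0.039), CEBPD fell by 1.94 (SE 0.24, adjusted p = 0.014), SRF, the factor behind the cytoskeletal program, fell by 1.19 (SE 0.14, adjusted p = 0.0087), and the cell cycle inhibitor CDKN1A fell by 1.13 (SE 0.17, adjusted p = 0.020). SERTAD1 fell by 0.98 (SE 0.09, adjusted p = 0.0011). Of 11462 probes, 3 were higher and 22 lower (1310 at an unadjusted p under 0.05). With arrays re-centred and scaled 52 were higher and 140 lower, and with a dye term 44 and 120. Without replicates 1, 2 and 3 of PDGF at 2 h the count was 6, 2 and 6. It was 9 without replicate 3 of PDGF at 4 h. The CCN2 call ended whichever replicate was left out. As lists, immediate-early transcription factors (median -0.70, list test adjusted p = 3.0e-08), NF-kB targets (median -0.47, list test adjusted p = 0.00013) and interferon response genes (median -0.43, list test adjusted p = 0.0015) were lower at 4 h, and ribosome biogenesis genes were higher (median 0.24, list test adjusted p = 6.7e-06). The immediate-early and the ribosome biogenesis lists had adjusted p = 0.28 with an estimated correlation, NF-kB targets had adjusted p = 0.45 with an estimated correlation, and interferon response genes had adjusted p = 0.47 with an estimated correlation.

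**Figure D2:**
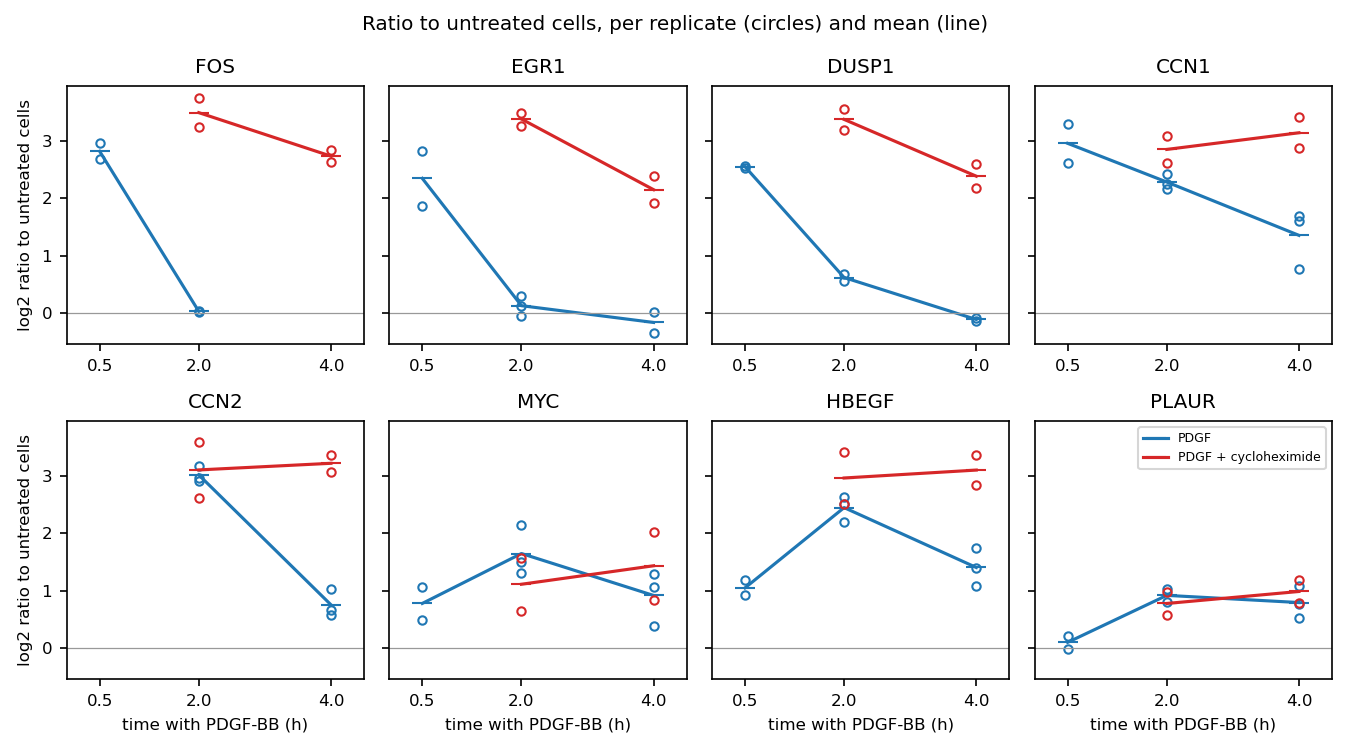
Log2 ratio to untreated cells of 8 panel genes against hours with PDGF-BB, circles for single replicates and lines for means, blue for PDGF and red for PDGF with cycloheximide. FOS went from 2.82 at 0.5 h to 0.03 at 2 h with PDGF alone and stood at 3.49 at 2 h with cycloheximide, while PLAUR was between 0.78 and 0.98 in all 4 conditions at 2 and 4 h.

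Cells given PDGF with cycloheximide for 2 h had high levels of inflammatory and immediate-early genes relative to untreated cells. The chemokine CXCL8 rose most (4.52 ± 0.78, n = 2, adjusted p = 0.00013, 22.9-fold), ahead of the NF-kB inhibitor TNFAIP3 (4.13 ± 0.97, adjusted p = 0.00016), NR4A2 (3.74 ± 0.81), GADD45B (3.73 ± 0.33, adjusted p = 2.9e-06), JUN (3.53 ± 0.31, adjusted p = 1.5e-07) and FOS (3.49 ± 0.36, adjusted p = 4.3e-07). LGR4, a receptor for R-spondins, fell most (-1.98 ± 0.11, n = 2, adjusted p = 0.00015), with CBR3 (-1.86 ± 0.07) and TRIM2 (-1.74 ± 0.43) next. PRMT2, an arginine methyltransferase, fell with the smallest spread (-1.39 ± 0.01, n = 2, adjusted p = 7.1e-08) among the 10 genes named as falling. In all, 1652 probes were higher and 1301 lower of 12804, 724 and 296 of them by at least 1.5-fold. The design holds no cells given cycloheximide without PDGF, so these values join the effects of both agents. Leaving out replicate 1 gave 1322 calls and leaving out replicate 2 gave 1714. HSPA8 (-1.46 ± 1.49, n = 2, adjusted p = 0.047) rested on replicate 2, without which it was at -0.40.

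Among the lists at 2 h with cycloheximide, immediate-early transcription factors had 26 of 30 higher and 4 not called (28 adjusted over the list alone, median 2.72, list test adjusted p = 9.1e-21, and adjusted p = 0.0078 with an estimated correlation). NF-kB targets had 20 of 23 higher (21 adjusted over the list alone, median 2.06, list test adjusted p = 1.8e-16). As a list they had adjusted p = 0.052 with an estimated correlation. Feedback inhibitors had 21 of 29 higher (21 adjusted over the list alone, list test adjusted p = 4.2e-12, and adjusted p = 0.0084 with an estimated correlation), and cytokines and chemokines 8 of 13 (11 adjusted over the list alone, list test adjusted p = 3.8e-07, and adjusted p = 0.0078 with an estimated correlation), such as CXCL3 (3.23 ± 0.20) and CCL2 (2.85 ± 0.78). Replication-dependent histones, measured here only in amplified polyadenylated RNA, had 5 of 7 higher (6 adjusted over the list alone, median 1.04, list test adjusted p = 1.6e-05). They were led by H2AC18 (1.77 ± 0.05) and H1-2 (1.56 ± 0.15), each with n = 2. SRF targets had 10 of 21 higher and 2 lower (13 and 2 adjusted over the list alone, list test adjusted p = 1.6e-05), with RHOB (2.53 ± 0.31) and VCL (2.17 ± 0.10) ahead, and adjusted p = 0.12 with an estimated correlation. Growth factors and matricellular signals had 8 of 18 higher and 1 lower (10 and 1 adjusted over the list alone, list test adjusted p = 4.9e-05), among them endothelin 1 (EDN1, 3.25 ± 0.35). That list had adjusted p = 0.15 with an estimated correlation. Sterol genes had 11 of 19 higher (11 higher and 1 lower adjusted over the list alone, list test adjusted p = 0.00034), with adjusted p = 0.15 with an estimated correlation. TGF-beta and BMP targets had 6 of 11 higher, such as ID3 (2.68 ± 0.70), with 6 adjusted over the list alone (list test adjusted p = 0.0024). Their test gave adjusted p = 0.076 with an estimated correlation. Matrix, protease and adhesion genes had 9 of 30 higher (12 higher and 1 lower adjusted over the list alone, list test adjusted p = 0.020), with adjusted p = 0.56 with an estimated correlation.

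The same comparison at 4 h gave the most calls of the 7. CXCL8 (4.65 ± 0.74, n = 2, adjusted p = 5.4e-05, 25.0-fold), TNFAIP3 (4.16 ± 0.93), GADD45B (3.86 ± 0.46) and ATF3 (3.53 ± 0.85) led the rises, joined by AMOTL2 (3.23 ± 0.26), a regulator of YAP signalling, and the proto-oncogene relative MYBL1 (3.20 ± 0.31). CBR3 (-2.16 ± 0.27, n = 2, adjusted p = 3.3e-06), MEGF9 (-2.05 ± 0.41), ZCCHC24 (-1.96 ± 0.07), the frizzled receptor FZD1 (-1.95 ± 0.50) and PRMT2 (-1.92 ± 0.13, adjusted p = 6.1e-09) fell. In all, 2569 probes were higher and 2065 lower of 13151, 1237 and 567 of them by at least 1.5-fold. Several stress genes also fell, among them TRIB3 (-1.92 ± 0.26, adjusted p = 0.011), DNAJB9 (-1.70 ± 0.31, adjusted p = 0.007), DDIT4 (-1.48 ± 0.64) and ASNS (-1.10 ± 0.60). Of 21 unfolded protein and amino acid response genes, 6 fell and 2 rose, with the same counts adjusted over the list alone, and the list test did not pass (median -0.35, adjusted p = 0.067). The calls of TRIB3, DNAJB9, DDIT4 and ASNS were lost when arrays were re-centred and scaled to a common spread. The total then was 2712, and it was 2836 without replicate 2.

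List calls at 4 h with cycloheximide did not hold where a correlation was estimated. NF-kB targets had 20 of 21 higher (21 adjusted over the list alone, median 2.37, list test adjusted p = 2.5e-12). The list then gave adjusted p = 0.10 with an estimated correlation. Immediate-early transcription factors had 25 of 30 higher (26 adjusted over the list alone, median 1.94, list test adjusted p = 1.5e-11), with adjusted p = 0.080 with an estimated correlation. Feedback inhibitors had 18 of 29 higher (19 adjusted over the list alone, list test adjusted p = 3.0e-08) and cytokines and chemokines 9 of 13 (10 adjusted over the list alone, list test adjusted p = 3.1e-05), each with adjusted p = 0.080 with an estimated correlation. Histones had 6 of 7 higher (7 adjusted over the list alone, median 1.15, list test adjusted p = 1.9e-05), from H1-2 (2.15 ± 0.69) to H2BC21 (1.15 ± 0.01), each with n = 2 and with no estimated correlation. Growth factors and matricellular signals had 12 of 20 higher (13 adjusted over the list alone, list test adjusted p = 1.9e-05) and SRF targets 15 of 21 higher and 1 lower (15 and 1 adjusted over the list alone, list test adjusted p = 0.00012), each with adjusted p = 0.17 with an estimated correlation. TGF-beta and BMP targets had 4 of 10 higher (4 adjusted over the list alone, list test adjusted p = 0.015), with adjusted p = 0.17 with an estimated correlation, and matrix, protease and adhesion genes had 13 of 31 higher and 1 lower (13 and 2 adjusted over the list alone, list test adjusted p = 0.015). This became adjusted p = 0.52 with an estimated correlation. Cytosolic ribosomal proteins had 5 of 31 lower, such as RPS14 (-0.66) and RPL22 (-0.53), with 5 adjusted over the list alone (median -0.17, list test adjusted p = 0.0030), and adjusted p = 0.36 with an estimated correlation.

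Direct arrays of PDGF with cycloheximide against PDGF alone asked what the inhibitor added at 2 h. TNFAIP3 (3.96 ± 0.99, n = 2, adjusted p = 0.00029, 15.6-fold), CXCL8 (3.73 ± 1.12), FOS (3.32 ± 0.28, adjusted p = 1.1e-06) and EGR1 (3.28 ± 0.87, adjusted p = 2.5e-05) were higher with cycloheximide, as were DUSP1 (3.00 ± 0.17, adjusted p = 3.5e-07) and ZFP36 (3.08 ± 0.26), whose product destabilises cytokine messages. The transcription factor MSC was lowest (-1.66 ± 0.64, n = 2, adjusted p = 0.0031), followed by LGR4 (-1.61 ± 0.16) and the small nucleolar RNA host SNHG3 (-1.46 ± 0.41). HBEGF was higher with cycloheximide (1.15 ± 0.46, adjusted p = 0.0041), while MYC (0.27 ± 0.47), PLAUR (-0.32 ± 0.34) and CCND1 (-0.08 ± 0.70) were not called at n = 2. Of 8848 probes, 922 were higher and 479 lower, 369 and 103 of them by at least 1.5-fold, and there were 338 calls with only its own 2 replicates in the fit. With arrays re-centred and scaled 606 were higher and 188 lower. Without replicate 1 there were 621 calls and without replicate 2 there were 815. Of the lists, immediate-early transcription factors had 21 of 26 higher (23 adjusted over the list alone, median 2.44, list test adjusted p = 1.4e-20, and adjusted p = 0.0068 with an estimated correlation) and feedback inhibitors 16 of 28 (18 higher and 1 lower adjusted over the list alone, list test adjusted p = 1.3e-09, and adjusted p = 0.039 with an estimated correlation). NF-kB targets had 13 of 19 higher (17 adjusted over the list alone, list test adjusted p = 6.4e-13). The test became adjusted p = 0.10 with an estimated correlation. Cytokines and chemokines had 4 of 10 higher (4 adjusted over the list alone, list test adjusted p = 0.0034), with adjusted p = 0.13 with an estimated correlation. Histones had 4 of 5 higher (5 adjusted over the list alone, list test adjusted p = 6.8e-06), led by H2AC6 (1.62 ± 0.11, n = 2). Growth factors had 7 of 16 higher and 1 lower (9 and 3 adjusted over the list alone, list test adjusted p = 0.0034) and sterol genes 6 of 14 higher (6 higher and 1 lower adjusted over the list alone, list test adjusted p = 0.026), each with adjusted p = 0.46 with an estimated correlation. Ribosome biogenesis genes had 3 of 20 lower, among them nucleolin (NCL, -0.40 ± 0.16), and 2 higher, ODC1 (1.19 ± 0.22) and RRP12 (0.92 ± 0.41), with 5 lower and 2 higher adjusted over the list alone (median -0.22, list test adjusted p = 0.017). For this list, limma gave adjusted p = 0.55 with an estimated correlation. Cytosolic ribosomal proteins had 2 of 30 lower (0 adjusted over the list alone in limma, list test adjusted p = 0.0061), with adjusted p = 0.46 with an estimated correlation.

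In the same direct comparison at 4 h, CXCL8 (4.47 ± 0.07, n = 2, adjusted p = 0.0001, 22.2-fold), TNFAIP3 (4.02 ± 0.59), the HLH protein ID3 (3.45 ± 0.75, adjusted p = 0.0016), GADD45B (3.42 ± 0.37) and FOS (3.19 ± 0.06, adjusted p = 6.9e-07) were higher with cycloheximide. The constitutive chaperone HSPA8 was lowest (-1.95 ± 0.43, n = 2, adjusted p = 0.011), then DDIT4 (-1.79 ± 0.47, adjusted p = 0.0086) and PRMT2 (-1.73 ± 0.15, adjusted p = 1.2e-08). MYC was higher (1.11 ± 0.36, adjusted p = 0.024), and PLAUR (0.05 ± 0.56) and CCND1 (0.76 ± 0.36, adjusted p = 0.056) were not called. AGPAT5 (-1.47 ± 0.18) was among 5 genes with probes called in opposite directions, of 64 genes with several called probes. Against PDGF alone at 2 h such genes were 2 of 13. For PDGF with cycloheximide against untreated cells they were 15 of 55 at 2 h and 27 of 121 at 4 h. With PDGF alone they were 0 of 8 at 2 h and 0 of 23 at 4 h. In all, 1963 probes were higher and 1266 lower of 12490, 964 and 298 of them by at least 1.5-fold. Without replicate 2 the count was 1569, and the HSPA8 call ended without either replicate.

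Of 23 ribosome biogenesis genes tested for cycloheximide against PDGF alone at 4 h, 12 were lower, 2 higher and 9 not called (13 lower and 2 higher adjusted over the list alone, median -0.42, list test adjusted p = 0.00034). The list test had adjusted p = 0.29 with an estimated correlation. CAD (-0.94 ± 0.27, adjusted p = 3.6e-05) and NOP56 (-0.73 ± 0.64) were lower and ODC1 was higher (1.35 ± 0.12), each with n = 2. Quiescence and FOXO targets had 9 of 27 higher and 1 lower (12 and 2 adjusted over the list alone, list test adjusted p = 0.024), with adjusted p = 0.61 with an estimated correlation. TXNIP (2.55 ± 1.63, n = 2, adjusted p = 0.014) varied widely between replicates and lost its call without replicate 2, whereas BCL6 (2.25 ± 0.39) and IRS1 (1.29 ± 0.19) were tighter. All 6 histone genes tested were higher (6 adjusted over the list alone, median 1.49, list test adjusted p = 1.1e-06), H2AC6 by 2.53 ± 0.38 (n = 2) after its fall with PDGF alone. NF-kB targets had 20 of 22 higher (20 adjusted over the list alone, list test adjusted p = 1.3e-13). This list had adjusted p = 0.086 with an estimated correlation. Immediate-early transcription factors had 24 of 29 higher (25 adjusted over the list alone, list test adjusted p = 1.3e-13), feedback inhibitors 15 of 25 (15 adjusted over the list alone, list test adjusted p = 5.9e-07) and cytokines 9 of 15 (11 adjusted over the list alone, list test adjusted p = 4.1e-05), each with adjusted p = 0.079 with an estimated correlation. Growth factors had 9 of 17 higher (9 adjusted over the list alone, list test adjusted p = 0.00056), SRF targets 8 of 21 higher and 1 lower (8 and 1 adjusted over the list alone, list test adjusted p = 0.0022) and ribosomal proteins 5 of 31 lower (5 adjusted over the list alone, list test adjusted p = 0.00031), each with adjusted p = 0.29 with an estimated correlation. TGF-beta and BMP targets had 6 of 10 higher and 1 lower (7 and 1 adjusted over the list alone, list test adjusted p = 0.020), with adjusted p = 0.24 with an estimated correlation. Interferon response genes had 5 of 17 higher, such as GBP1 (2.94) and IRF1 (2.90), with 5 adjusted over the list alone (list test adjusted p = 0.033). The list had adjusted p = 0.61 with an estimated correlation.

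**Figure D3:**
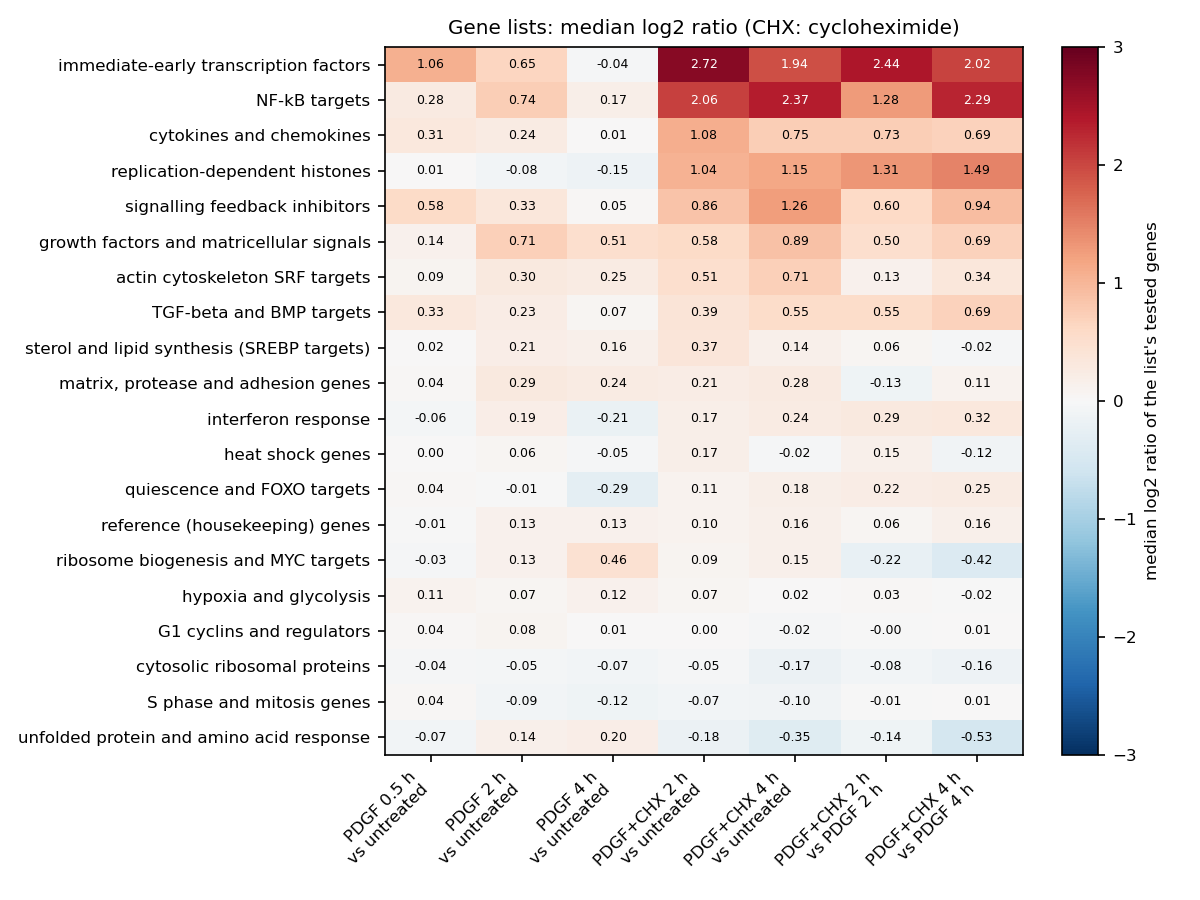
Median log2 ratio of the tested members of 20 gene lists (vertical) in the 7 comparisons (horizontal), red for higher and blue for lower in the first-named condition. Immediate-early transcription factors went from 1.06 at 0.5 h to -0.04 at 4 h of PDGF and to 2.72 at 2 h with cycloheximide, and ribosome biogenesis genes went from 0.46 with PDGF at 4 h to -0.42 for cycloheximide against PDGF alone.

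The cycloheximide effect itself changed between 2 and 4 h for a limited set of probes. Of 8383, it was higher at 4 h for 96 and lower for 15 (1139 at an unadjusted p under 0.05). It was higher for 274 and lower for 57 with a dye term, 414 and 174 in 1 model of the 6 RNA conditions, and 33 and 1 with arrays re-centred and scaled. KLF5 differed most (2.88, SE 0.55, adjusted p = 0.029): it was lower with cycloheximide at 2 h (-1.28 ± 0.07, n = 2, adjusted p = 0.046, lost without either replicate) and higher at 4 h (1.61). MYBL1 (1.93, SE 0.27), SOCS5 (1.73, SE 0.27) and GBP1 (1.72, SE 0.33) had a higher cycloheximide effect at 4 h than at 2 h. The effect on RASD1 fell by 1.90 (SE 0.25, adjusted p = 0.013), and that on EIF2AK3, a sensor of unfolded proteins, fell by 1.20 (SE 0.16, adjusted p = 0.0082). As lists, NF-kB targets (median 0.63, list test adjusted p = 0.00096) were higher and ribosome biogenesis genes (median -0.20, list test adjusted p = 0.0081) lower, each with adjusted p = 0.60 with an estimated correlation. With the comparison's own replicates alone limma called 0 probes (919 at an unadjusted p under 0.05), and without replicate 2 of the 2 h comparison it also called 0 (941 at an unadjusted p under 0.05). Without replicate 1 or 2 of the 4 h comparison it called 22 and 21.

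Sorting induced probes by time and by cycloheximide gave 428 probes of 386 genes. The early class held 29 probes of 28 genes, among them 14 of 31 immediate-early transcription factors on the array (such as FOS, EGR1, KLF6 and SRF) and 5 of 32 feedback inhibitors (DUSP1, DUSP5, ZFP36, GADD45B and TRIB1). With cycloheximide 24 of 24 tested early probes were higher than with PDGF alone at 2 h, and 24 of 24 at 4 h. Their median went from 1.64 at 0.5 h to 0.03 at 4 h of PDGF, and was 2.33 at 4 h with cycloheximide. Of 399 later probes, 229 were resistant, 44 sensitive and 126 undecided. Of these, 176, 37 and 83 had a test at 0.5 h, so the others cannot be said to have risen only later. Since no cells received cycloheximide alone, a resistant call does not show that PDGF raised a gene without new protein. Resistant genes included CCN2, NR4A3, DKK1, HBEGF, IL7R, VCL, MAFF and RCAN1, 8 of 33 matrix, protease and adhesion genes, 8 of 25 NF-kB targets and 5 of 25 growth factors and matricellular signals. Of the genes named, CCN2, NR4A3, DKK1 and IL7R had no test at 0.5 h, and RCAN1 stood at 1.81 there without a call. Sensitive genes included the collagenase MMP13, COL8A1, PDLIM5, EMP1 and TBX2, and 5 of 27 ribosome biogenesis genes on the array (NOP56, DKC1, WDR12, MRTO4 and SRM). A further 3 ribosome biogenesis genes were resistant. At 4 h, 39 of the 44 sensitive probes were tested with cycloheximide against untreated cells, and MMP13 was not. No gene of the other lists was sensitive, but MMP13 and COL8A1 were not on the matrix list. A gene with several probes counted as early or resistant before sensitive. Whether lists differed in their share of sensitive genes was not tested. KLF5, PDLIM5, EMP1 and TBX2 counted as sensitive on their 2 h values alone. Against PDGF alone at 4 h, KLF5 was higher with cycloheximide (1.61). PDLIM5 (-0.13, adjusted p = 0.61), EMP1 (-0.46, adjusted p = 0.070) and TBX2 (0.10, adjusted p = 0.77) were not called there by limma. At 4 h with cycloheximide PDLIM5 was still above untreated cells (0.53, adjusted p = 0.025), under the ratio limit. Of the 44 sensitive probes, 31 were induced at 4 h and not at 2 h, against 54 of the 229 resistant ones. The class rule can favour this, and the difference was not tested. A probe induced at both times was resistant if it passed at either, and 73 resistant and 5 sensitive probes were induced at both. Cycloheximide against PDGF alone, which a sensitive call needs, was tested for 8848 probes at 2 h and 12490 at 4 h.

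**Figure D4:**
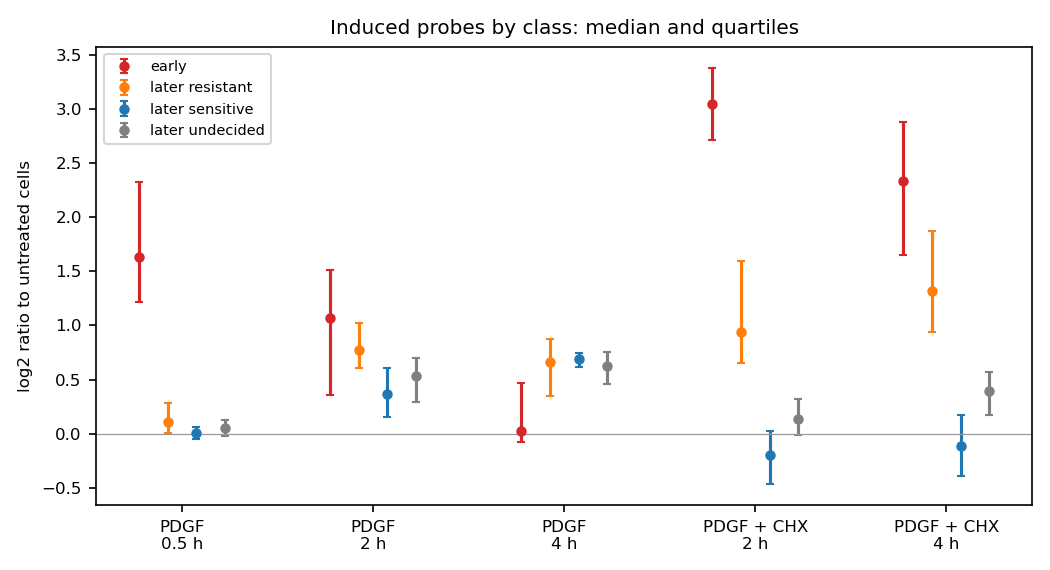
Median log2 ratio to untreated cells (points) with lower and upper quartiles (bars) of early, later resistant, later sensitive and later undecided probes in the 5 comparisons with untreated cells. Early probes peaked at 3.05 with cycloheximide at 2 h, resistant ones reached 1.32 with cycloheximide at 4 h, and sensitive ones lay at -0.19 and -0.11 with cycloheximide, where the class rule itself keeps them low.

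Part of the later response was higher with cycloheximide than with PDGF alone. Of 192 resistant probes tested at 2 h, 76 were higher with cycloheximide than with PDGF and 5 lower, and of 214 tested at 4 h, 159 were higher and 0 lower in limma. The class rule favours this, since resistant probes were chosen for being high with cycloheximide. A difference between early and later genes in this respect was not tested. Of all probes induced by PDGF at 2 h, whatever their class, 222 were tested against cycloheximide, 85 higher, 17 lower and 120 not called (median 0.35). At 4 h, 76 of 217 were higher, 32 lower and 109 not called (median 0.24). Many genes were raised with cycloheximide that PDGF alone did not call: of 692 probes higher against both references at 2 h, 535 had no PDGF call, and of 1482 at 4 h, 1173 had none. Without cycloheximide-only cells these cannot be assigned to PDGF. The resistant and sensitive classes held 61 and 6 probes at a ratio of at least 2, and 631 and 157 with no ratio limit. Without replicate 2 in every comparison limma called 0 probes with PDGF alone (264, 1394 and 1864 at an unadjusted p under 0.05 at 0.5, 2 and 4 h), and the classes were empty.

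Over the 7 comparisons 70 of 157 list tests passed. Of 140 with an estimated correlation 8 passed: immediate-early transcription factors at 0.5 h and in both 2 h comparisons with cycloheximide, feedback inhibitors in the same 3, and cytokines and chemokines at 0.5 h and at 2 h with cycloheximide against untreated cells. Replicates on the smaller table were not used in the calls. Its dye-exchanged arrays correlated across genes, which are not independent replicates, at -0.63 for PDGF at 0.5 h and between -0.17 and 0.19 for the others, so the signs there are a weak check. All 27 genes called higher at 0.5 h that it held were also positive there, FOS at 1.96 and NR4A2 at 2.23. In the 4 cycloheximide comparisons between 93.3% and 93.5% of genes called higher, and between 87.7% and 94.7% of those called lower, kept their sign, against between 64.3% and 67.6% of genes not called. KLF5 for cycloheximide against PDGF at 2 h was at 0.04 there and SLC25A36 for cycloheximide against untreated cells at 2 h at -0.06. Marker lists of other cell types held few calls: of 4 leukocyte, 7 epithelial and 5 astrocyte and glia markers tested at 2 h of PDGF, limma called 0. Of 8 neuron markers, 2 rose, NEFM (0.59 ± 0.23, n = 3, adjusted p = 0.004) and SNAP25 (0.55), with 2 adjusted over the list alone, and the list test did not pass (adjusted p = 0.077).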

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

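No test in this part was chosen only after its result was seen, but the neighbouring gene pairs were named after their values were seen.

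The 3 differences between time points came from contrasts tested within the same fit, and each stands out as a difference between groups of samples. Between PDGF at 2 h and at 0.5 h, 7 probes differed, with FOS at -2.79 and DUSP1 at -1.93 on the log2 scale. Between PDGF at 4 h and at 2 h, 25 probes differed, with CCN2 at -2.26. The cycloheximide effect differed between 4 h and 2 h for 111 probes.

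Few probes were called at 0.5 h of PDGF, 30 against 739 at 2 h. Fewer replicates as the whole cause were argued against. Leaving out 1 of the 3 replicates at 2 h still gave between 100 and 424 calls, above the 60 set as a limit. Those counts lay below 739, so a part played by fewer replicates at 0.5 h was not excluded. Replicate 2 left out of every comparison left 1 replicate in 5 of the 7. That fit gave 0 calls at 2 h in limma (1394 at an unadjusted p under 0.05). Dye bias on the 0.5 h arrays was left undecided. A dye effect per probe, shared by all arrays of the fit, gave 60 calls at 0.5 h, below the limit of 200. Such a shared effect cannot capture a bias particular to the 0.5 h arrays, and the dye-exchanged arrays of replicate 1 correlated at -0.36 across genes. Whether responses had not yet developed at 0.5 h stays open: of 182 probes induced at 2 h and not at 0.5 h, a choice that itself favours a difference, 4 were called higher at 2 h than at 0.5 h (135 at an unadjusted p under 0.05, median difference 0.65, median SE 0.22), where at least 60 had been asked for and simulated data with the observed differences gave between 10 and 31. Over all probes the same contrast gave 4 higher, against 163 with arrays re-centred and scaled, 82 with a dye term and 77 with only its own replicates, so the count depends on the processing.

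Among 12221 placed genes that were tested, induced genes were next to each other in genome order more often than random genes. Genes that were not tested were skipped, so a pair may have other genes between them. Random sets were not matched for how often a gene was measured. Among 386 induced genes 28 neighbouring pairs were found, against a median of 12 in 10000 random sets of the same size (upper limit 19, one-sided permutation p = 2e-04), which argues against chance placement. Pairs with the same letters before the first digit of their symbols did not account for it. Without them (GBP1 with GBP2 and CAV1 with CAV2) 26 pairs remained (upper limit 19). Relatedness was judged from symbols alone, and sequence similarity or overlap of neighbouring genes was not examined. Of the 28 pairs, 0 had probe numbers within 100 of each other on the array. Pairs included PLAU with VCL, TRIB1 with MYC, EGR1 with ETF1 and SOD2 with WTAP. No biological explanation was tested, and shared regulation of neighbours may be followed up as a hypothesis.

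Other assignments of the samples were too few for a share under 0.05. For PDGF at 2 h the real assignment gave 739 calls and the highest other gave 2, so that 1 of 4 assignments reached as many. For PDGF at 4 h it gave 1738 and the highest other 149, again 1 of 4. For PDGF at 4 h against 2 h it gave 25 and the highest other 1, so that 1 of 10 splits reached as many.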

How the results depend on the processing

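Tests chosen only after the data were seen are the use of either dye orientation, the crossed replicate block and 1 probe per gene. Among single genes, 11732 of 12778 values for 955 results kept their side of the threshold, 831 became weaker, 215 became stronger and 0 changed direction. Among gene lists 658 of 815 values for 221 results were kept, 131 became weaker, 25 became stronger and 1 changed direction: signalling feedback inhibitors between 0.5 and 2 h of PDGF pointed upward in fry (adjusted p = 0.999) and downward in the list test (adjusted p = 0.0136). For genes and lists alike, a change of direction was counted only where the main fit had a call. Genes named for the largest change in a comparison had the same sign in every replicate, so leaving out a replicate could not turn them. Robust empirical Bayes and 1 probe per gene kept the coefficient itself. The absence of changed directions among genes was thus in part set by these choices. Values without a test in an alternative were left out. With an estimated correlation 8 list tests passed, against 70. Robust empirical Bayes, either dye orientation and 1 probe per gene kept every count within 1.5 times. No signal over background is in the files, so the limit it sets was not measured. Architecture by class was not run. The cause of the changes below was not tested, except where fewer probes or fewer replicates are the construction.

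With arrays re-centred and scaled, the counts were 67 for PDGF at 0.5 h (57 higher and 10 lower, against 29 and 1), 2349 at 2 h (1338 and 1011, against 533 and 206), 2712 for cycloheximide against untreated cells at 4 h, and 794 for cycloheximide against PDGF at 2 h (606 and 188, against 922 and 479). They were 207 for PDGF at 2 h against 0.5 h (163 and 44, against 4 and 3), 192 for 4 h against 2 h (52 and 140, against 3 and 22), 34 for the change of the cycloheximide effect (33 and 1, against 96 and 15), and 51 early probes.

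With only probes on every array, fewer probes gave 18, 451 and 834 calls for PDGF at 0.5, 2 and 4 h. Cycloheximide gave 1288 and 2080 against untreated cells and 793 and 1597 against PDGF. The differences gave 2 from 0.5 to 2 h and 55 for the cycloheximide effect, and the classes held 17 early, 110 resistant and 23 sensitive probes.

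With the replicate number as a block, PDGF at 0.5 h gave 16 calls, cycloheximide at 2 h gave 1925 against untreated cells and 925 against PDGF, PDGF at 4 h against 2 h gave 16, and 16 probes were early. Deviations of replicates with the same number correlated across genes, which are not independent replicates, between -0.58 and 0.51, above 0.1 in 8 of 21 pairs of comparisons. The highest was between the 4 h cycloheximide comparisons, and both cycloheximide comparisons with untreated cells had 0.49. These pairs have an RNA condition in common, but so do PDGF and cycloheximide against untreated cells at 4 h (-0.20). Whether RNA was shared by number was not settled. The main fit did not pair samples by number and took replicates of different comparisons as independent. The lowest of these correlations was between cycloheximide against PDGF at 2 h and cycloheximide against untreated cells at 2 h. The former also had -0.48 and -0.29 with cycloheximide at 4 h against PDGF and against untreated cells, so its numbers are in doubt. With those 2 numbers exchanged, the crossed replicate block gave 20 calls for PDGF at 2 h against 0.5 h and 175 for the cycloheximide effect.

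In 1 model of the 6 RNA conditions, PDGF at 2 h gave 1252 calls, cycloheximide against PDGF at 2 h gave 2222, and the differences gave 18, 88 and 588. With only a comparison's own replicates, PDGF gave 55, 1462 and 0 calls at 0.5, 2 and 4 h (limma, 2368 at an unadjusted p under 0.05 at 4 h, lowest adjusted p = 0.0825). Cycloheximide then gave 1536 and 2724 against untreated cells and 338 against PDGF at 2 h, PDGF at 2 h against 0.5 h gave 103, and the change of the cycloheximide effect gave 0 (limma, 919 at an unadjusted p under 0.05). With a dye term on single arrays, PDGF gave 60 and 1182 calls at 0.5 and 2 h, the differences gave 104, 164 and 331, and 55 probes were early. With both tables joined, PDGF at 2 h against 0.5 h gave 24. A ratio of at least 2 gave 61 resistant and 6 sensitive probes, and no ratio limit gave 631 and 157.

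Leaving out each replicate in turn, with the lone sample of a pair assumed to vary like the other groups, gave between 6 and 11 calls for PDGF at 0.5 h, between 100 and 424 at 2 h and between 716 and 1606 at 4 h. Cycloheximide gave between 1322 and 1714 and between 2836 and 3297 against untreated cells at 2 and 4 h, and between 621 and 815 and between 1569 and 2231 against PDGF. The differences gave between 3 and 6, between 2 and 33 and between 0 and 112 in limma (941 at an unadjusted p under 0.05 where the count was 0). The classes held between 0 and 24 early, 0 and 197 resistant and 0 and 54 sensitive probes, empty where replicate 2 was left out of every comparison (264, 1394 and 1864 at an unadjusted p under 0.05).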

Other observations

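No test in this part was chosen only after its result was seen. Genes that fell with PDGF fell with cycloheximide present as well in part of the cases. Of 200 probes lower at 2 h of PDGF and tested in both, 89 were also lower with cycloheximide (44.5%, 21.6 expected of independent calls), and of 761 lower at 4 h, 382 were (50.2%, 134 expected). Of those higher, 348 of 510 at 2 h (68.2%, 68.7 expected) and 464 of 871 at 4 h (53.3%, 178 expected) were also higher with cycloheximide. In 20 simulations without effects, with untreated RNA shared between comparisons, limma gave 0 shared higher calls and at most 4 calls in any comparison, too few to show what sharing adds where many probes are called.

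Of 510 probes higher at 2 h of PDGF, 263 were higher at 4 h too, and of 204 lower, 123 were lower at 4 h. Both comparisons are ratios to untreated cells, and what a shared reference adds to these overlaps was not tested. Measured directly and through untreated cells, the cycloheximide effect correlated across genes, which are not independent replicates, at 0.853 over 8213 probes at 2 h and at 0.910 over 9895 probes at 4 h.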
